A study of Mus musculus with 15 samples.

How the data were processed

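H3K27ac ChIP-seq was measured in 8 samples of mouse cells, 2 each of embryonic stem cells (ESC), cells labelled as epiblast-like (EPISC), trophoblast stem cells (TSC) and extra-embryonic cells (XEN), with 7 input samples, 2 per type except 1 for TSC. Per the labels' protocols, chromatin was crosslinked with formaldehyde, sonicated, precipitated with an antibody against H3K27ac (ab4729) and made into sequencing libraries. Groups were taken from the labels.

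The authors deposited 4 peak lists, 1 per cell type, which the labels of both replicates name. Each holds a chromosome, a start and an end per peak, with no height, fold or score. Per the submitters' processing notes, the build was mm10 and the tools included Bowtie2 2.3.4.1, MACS2 2.1.1, SAMtools, bedtools and Picard. Their order and settings, the peak threshold, the use of the inputs, and whether peaks were called on pooled reads or combined from both replicates are not given in the sources used here. A cell type with deeper sequencing or a better ChIP can have more and wider peaks, so list sizes are not comparable between cell types without that knowledge. The signal tracks that the labels name for single replicates, and the inputs, were not analysed here, and the depth is unknown. The lists give no replicate spread, so no test between cell types was made. Exact (Clopper-Pearson) 95% intervals of shares cover counting error only. The 95% intervals of log2 width ratios come from resampling regions, and leave out the spread between chromosomes and between replicates.

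Peaks never passed the end of a chromosome of GRCm38, the assembly known as mm10, and its sequence and the GENCODE M21 annotation were used. Coordinates are printed counted from 1. Overlapping or touching peaks of the 4 lists were merged into 44231 regions, and each was classed by the lists with a peak in it. A peak or region was shared if it overlapped by 1 bp or more, and specific to a cell type if no other list had a peak there. Promoter regions lay within 2.5 kb of a transcript start of any of 21911 protein-coding genes, and all others were distal. Introns, exons and intergenic places refer to the middle of a region and to protein-coding genes only, so an intergenic place can lie in a gene of another type. Overlaps were compared with 1000 circular shifts of one list within each chromosome.

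Before the data were examined, 12 gene lists of 12 to 22 genes were fixed. They covered naive, general and primed pluripotency, trophoblast, primitive endoderm, fibroblast (feeder cell), neural, blood and housekeeping genes, and targets of FGF and ERK, of WNT, and of NODAL and BMP signalling. For each list and cell type, the members with a specific region within 50 kb of the gene's annotated 5′ end were counted. That count was set against 10000 random lists of protein-coding genes, drawn to the same bins of the number of regions within 50 kb, planned as deciles, of which ties left 8 bins. A list was called apart if no more than 1 random list in 1000 had as many, or no more than 1 in 1000 as few. The annotated 5′ end can lie far from the promoter in use, as for Esrrb, Fgfr2 and Runx1. Neighbouring members such as Zic2 and Zic5, Krt8 and Krt18, Dppa2 and Dppa4 or Col4a1 and Col4a2 share regions, and genes can belong to more than 1 list. ESC and EPISC were also compared with each other alone in the same way.

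Named genes followed a rule fixed in advance. It took up to 8 members per gene list by the length of specific regions within 50 kb, members of the lineage lists with no peak in their own cell type, and the 10 genes per cell type with the longest specific regions whose nearest gene start is theirs and within 100 kb. It took the same for ESC-only and EPISC-only peaks, and the 5 largest clusters per cell type. Genes outside the rule (Pou5f1, Otx2, Klf5, Tfap2a, Gata6, Nid1, Ttr, Dab2, Ncor1, Pum1, Otud5, Foxd3, Cdh2, Zic2, Zic5, Hnf4a, Adamts9, Col4a1 and the genes under the widest peaks) were chosen after their values were seen. Motifs were 20 consensus sequences matched exactly on either strand in the central 1 kb of distal specific regions. Background regions were drawn 1000 times from the distal specific regions of the other 3 types to the same 10 GC bins, and a motif stood apart outside all draws. A consensus match is not binding, and related factors share a consensus. Peaks within 12.5 kb were joined into clusters.

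Settings were also varied, as fixed before the data were seen, to the wider 50% of each list, all lists reduced to the 16873 widest peaks, sharing defined as 50% of the peak covered or as a peak within 1 kb, promoter distances of 1 and 5 kb, gene windows of 20 and 100 kb, distal specific regions only, no matching of random lists, a motif window of 500 bp, no GC matching, a joining distance of 5 kb and clusters of distal peaks. Width stood in for the missing peak score. Alternatives added after seeing the data were the exact distribution of list counts, neighbouring members counted once, and motif matches outside repeat-masked bases. Analyses ran in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. On simulated data, all 6000 regions of known class were recovered, but these were placed apart, so the merging of close peaks was not tested. Among 2000 random gene lists of 20 genes 0.1% were called, and 99% of 200 lists with odds of a nearby region raised 20 times were called. A motif planted in an extra 10% of sequences was detected in 95% of 20 sets, and in none of 20 sets without it.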

Results

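H3K27 acetylation (H3K27ac), a histone modification carried by active promoters and enhancers, was mapped by ChIP-seq in 4 mouse stem cell types. Embryonic stem cells (ESC) stand for the naive pluripotent epiblast. The cells named EPISC are labelled as resembling epiblast stem cells, which stand for a later, primed epiblast. Trophoblast stem cells (TSC) give rise to the placental lineage. XEN cells are labelled as extra-embryonic, and XEN is the usual name of lines derived from the primitive endoderm. The series held 15 samples, of which 8 were ChIP samples, 2 per cell type, and 7 were inputs. The values analysed here were 4 peak lists, 1 per cell type, each named by the labels of both replicates. The ESC list held 26399 peaks covering 69.1 Mb of the mm10 genome, the TSC list 23986 peaks covering 56.4 Mb, the XEN list 19417 peaks covering 52.2 Mb and the EPISC list 16873 peaks covering 34.1 Mb. Median peak widths were 1810 bp in ESC, 1660 bp in EPISC, 1817 bp in TSC and 1975 bp in XEN. The lists gave positions without heights or scores, and the sequencing depth behind them is unknown. No difference between cell types was set against replicate error, since the lists do not separate the replicates and signal tracks of single replicates were not analysed here. Every comparison describes these 4 lists. Intervals of shares are exact binomial 95% intervals and cover counting error only.

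The series set out to describe active enhancers and promoters in each cell type. Most regions merged from the 4 lists had a peak in 1 list alone, and those in all 4 were mostly promoters. Merging the lists gave 44231 regions. Of these, 58.3% (interval 57.9 to 58.8) had a peak in 1 list, 15.0% in 2, 7.22% in 3 and 19.4% in all 4. ESC held 9872 specific regions, meaning regions with a peak in that list only, TSC 6936, XEN 5873 and EPISC 3113. This order did not hold with every list reduced to its 16873 widest peaks, where ESC held 6151, XEN 5619, EPISC 4626 and TSC 4138. That number is the size of the EPISC list, which kept all its peaks. Its specific regions rose only because narrower peaks of the other lists were dropped. In the full lists, specific regions were a minority of each list's peaks, which numbered 26399 in ESC, 23986 in TSC, 19417 in XEN and 16873 in EPISC. Within 2.5 kb of a transcript start of a protein-coding gene lay 90.1% (89.5 to 90.8) of the regions in all 4 lists, against 13.1% (12.7 to 13.5) of the regions in 1 list. The promoter share rose with the number of lists, through 22.8% for 2 and 45.6% for 3. The smallest list was the richest in promoters, with 60.8% of EPISC peaks against 42.6% of ESC peaks. Of 21911 protein-coding genes, 8948 (40.8%) had a promoter peak in all 4 lists and 8771 in none. A promoter peak in 1 list only was found at 581 genes for ESC, 425 for TSC, 403 for EPISC and 339 for XEN. Distal specific regions lay in introns for 53.9% in TSC, 49.4% in ESC and 38.0% in EPISC. In EPISC, 59.4% of them were intergenic, meaning outside protein-coding genes.

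**Figure D1:**
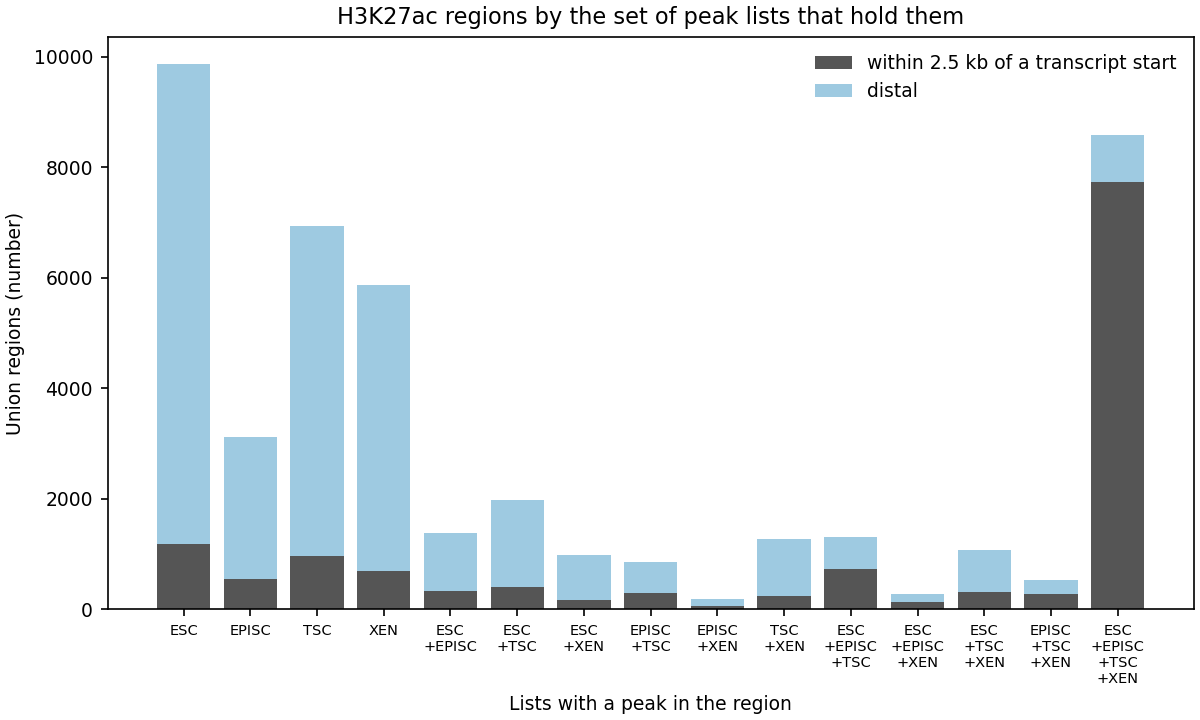
Bars give the number of merged H3K27ac regions (vertical axis) for each set of lists with a peak in them (horizontal axis), split into regions within 2.5 kb of a protein-coding transcript start (dark) and distal regions (light). The 9872 regions of ESC alone are mostly distal, while 7743 of the 8590 regions in all 4 lists lie at promoters.

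Between pairs of cell types, promoter peaks were largely shared and distal peaks were not. At promoters, between 75.6% and 89.4% of the peaks of a list overlapped a peak of another list by 1 bp or more. Of distal peaks, between 15.5% and 45.4% did. Distal EPISC peaks overlapped the ESC list at 45.4% (44.2 to 46.6), the TSC list at 39.3% (38.1 to 40.4) and the XEN list at 24.4% (23.3 to 25.4). Distal TSC peaks overlapped the ESC list at 36.1% and the XEN list at 27.8%. Distal XEN peaks overlapped the TSC list at 33.6%, the ESC list at 30.4% and the EPISC list at 15.5%. Over all peaks, the largest overlap was that of EPISC peaks with the ESC list, 71.3%. After 1000 random shifts of one list along each chromosome, no pair overlapped at more than 7.62% of peaks. The Jaccard index of covered bases ranged from 0.219 for ESC and XEN to 0.300 for EPISC and TSC, against at most 0.0208 after shifting. These shares depend on list size, and with every list reduced to its 16873 widest peaks, EPISC peaks overlapped the ESC list at 49.1% and the TSC list at 57.9%, in the opposite order.

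Most naive pluripotency genes had ESC-specific acetylation nearby, without reaching the threshold for calling a list apart. Of 18 genes of the naive network, 16 had an ESC-specific region within 50 kb of the gene start, where random lists of genes with similar numbers of regions nearby had a median of 11. All 18 had an ESC promoter peak, against 7 in EPISC, 10 in TSC and 9 in XEN. The specific regions covered 24.5 kb around Tet2, a DNA demethylation enzyme, and 23.1 kb around Dppa5a, at which no other list had a peak within 50 kb. They covered 18.2 kb around Klf2 and 18.1 kb around Nr5a2, transcription factors of the naive network, 13.8 kb around Tbx3 and 13.6 kb around Prdm14. Around Lifr, the receptor subunit through which LIF maintains ESC, the ESC-specific region covered 7.71 kb, and XEN-specific regions covered 17.1 kb. Of 10000 random lists, 99.62% had fewer members with an ESC-specific region, short of that threshold, set at no more than 1 random list in 1000 with as many. The value passed the threshold with the wider 50% of each list (99.99%), with lists of equal size (100%) and without matching (100%). It was lower with other peaks allowed within 1 kb (98.73%), with distal specific regions only (98.2%) and with a window of 100 kb (98.04%). The widest ESC peak, 52.9 kb on chromosome 12 (86461627 to 86514557), lay inside Esrrb, an orphan nuclear receptor of the naive network. The TSC list covered 19.9 kb of it, and the EPISC and XEN lists none. Since TSC peaks overlapped it, this peak was not ESC-specific, and it also lay outside the window around the annotated 5′ end of the gene. Esrrb and Klf5 were the 2 naive genes without an ESC-specific region.

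Most general pluripotency genes had promoter acetylation in both pluripotent types, and many had it in TSC as well. All 14 had an ESC promoter peak and 12 had one in EPISC, against 10 in TSC and 6 in XEN. Around Pou5f1, which encodes OCT4, peaks covered 29.4 kb within 50 kb in ESC, 20.7 kb in EPISC, 10.2 kb in TSC and 3.83 kb in XEN. Around Nanog, they covered 52.1 kb in ESC, 16.2 kb in EPISC, 8.41 kb in TSC and 10.3 kb in XEN. Around Sox2 the lengths were 19.9 kb in ESC and 9.42 kb in EPISC, with 1 TSC peak and no XEN peak. Specific regions lay near 11 of the 14 in ESC, with 88.2% of random lists lower, and near 4 in EPISC, with 69.3% lower. Neither stood apart.

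Primed epiblast genes were marked in EPISC, and most had peaks in ESC as well. Of the 17 genes, 14 had an EPISC promoter peak, against 10 in ESC, 6 in TSC and 6 in XEN. Within 50 kb, 16 had an EPISC peak and 14 an ESC peak. Of 17 such genes, 9 had an EPISC-specific region within 50 kb, against a median of 3 in random lists, and 99.91% of random lists were lower. Fgf5, a growth factor of the postimplantation epiblast, had 3 EPISC-specific regions covering 9.23 kb, and Wnt3, a ligand of primitive streak formation, had 2 covering 9.71 kb. No other list had a peak within 50 kb of either gene. EPISC-specific regions covered 12.8 kb around Lef1, a transcription factor of WNT signalling, 4.05 kb around Fgf8 and 3.93 kb around Pou3f1, and others lay near Sall2, Nodal and T. Otx2 had no EPISC-specific region, since its EPISC peaks overlapped ESC peaks, which covered 35.3 kb there. Sox3 was the primed gene without any EPISC peak within 50 kb. The call was marginal. It was lost in the exact distribution over all matched lists (99.8999%), with Zic2 and Zic5, whose starts lie close together, counted once (99.89%), with lists of equal size (99.89%), with other peaks allowed within 1 kb (99.6%), and with windows of 20 kb (99.69%) or 100 kb (99.25%).

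Trophoblast genes had TSC-specific regions nearby more often than the random median, without reaching the threshold. Of 22 genes, 17 had such a region within 50 kb, against a median of 11, and 99.62% of random lists were lower. The value passed the threshold with distal specific regions only (99.97%) and with a window of 100 kb (99.93%). A TSC promoter peak was present at 19 genes, against 12 in ESC, 10 in XEN and 8 in EPISC. TSC-specific regions covered 16.1 kb around Elf5, 15.6 kb around Hand1, 12.2 kb around Gata2, 11.8 kb around Ets2, 11.3 kb around Cdx2 and 10.4 kb around Gata3, all transcription factors of the trophoblast lineage. They also covered 5.29 kb around Bmp4, where no other list had a peak within 50 kb. Tfap2a, another member, had 6 ESC-specific regions and no TSC-specific region. Esx1 had no peak in any list within 50 kb.

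Primitive endoderm genes gave the clearest grouping of the lists fixed in advance. Of 22 genes, 18 had a XEN-specific region within 50 kb, against a median of 7, and all 10000 random lists were lower. A XEN promoter peak was present at 19, against 9 in TSC, 8 in ESC and 6 in EPISC. XEN-specific regions covered 38.9 kb around Foxa2, 28.8 kb around Sox17, 28.0 kb around Hnf1b and 14.2 kb around Sox7, transcription factors of endoderm, and also lay near Gata4. Around Foxa2, Sox17 and Sox7, no other list had a peak within 50 kb. The regions covered 24.1 kb around Lama1 and 15.1 kb around Lamb1, which encode laminin chains of the basement membrane, and 23.0 kb around Cubn, an endocytic receptor of visceral endoderm. Amn had no peak in any list. ESC-specific regions lay near 3 of the 22, Gata6, Nid1 and Ttr, a lower count than in every matched random list. That depletion fell short of the threshold with the wider 50% of each list, where 3.77% of random lists were as low, with lists of equal size (1.62%), with a 20 kb window (1.78%) and without matching (0.92%). EPISC-specific regions lay near none of the 22, as in 0.87% of random lists. The matching counts regions of all 4 lists, XEN-specific ones included, so it can raise the numbers expected for ESC and EPISC. These low counts of specific regions are also not a lack of peaks. Of the 22 genes, 15 had an ESC peak and 8 an EPISC peak within 50 kb.

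**Figure D2:**
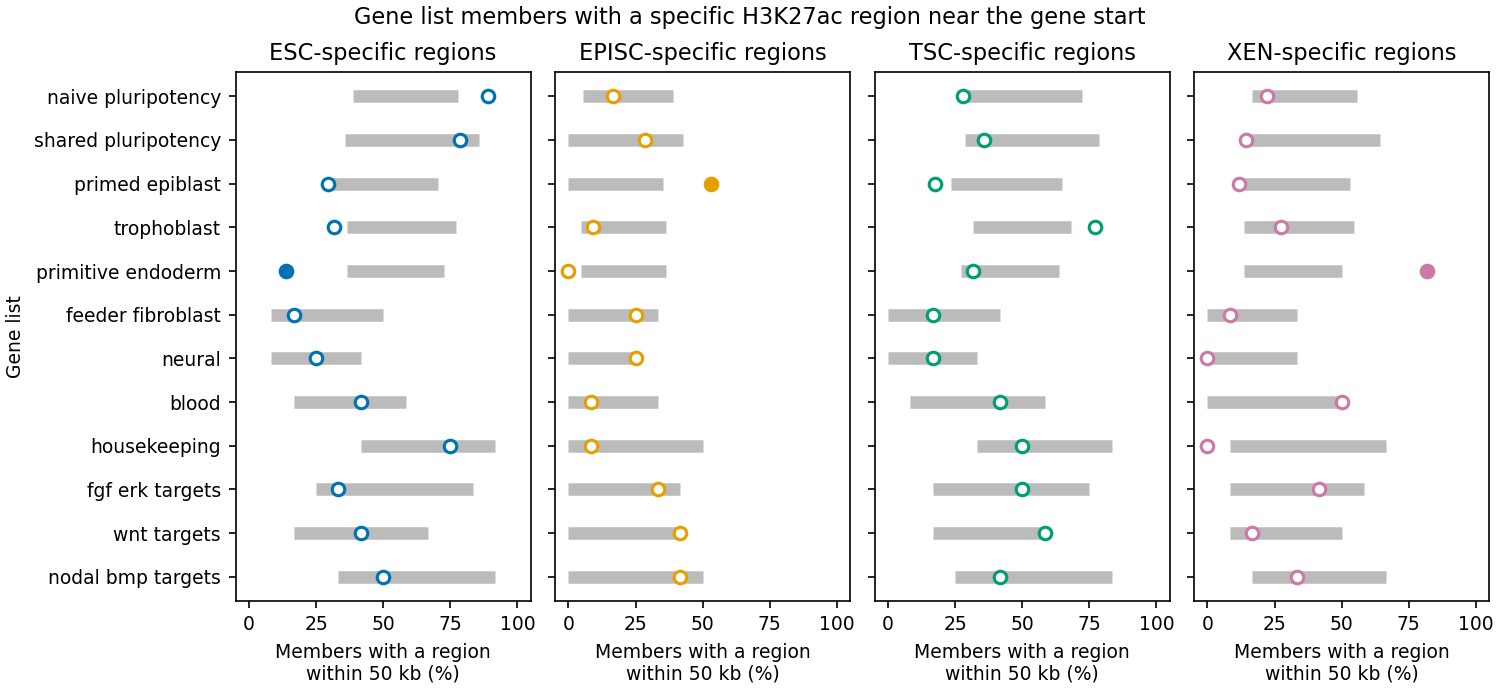
Circles give the share of each gene list's members (percent, horizontal axis) with a specific region of a cell type within 50 kb of the gene start, 1 panel per cell type. Grey bars span the central 95% of 10000 matched random lists, and filled circles mark lists past the threshold in these draws. They are primed epiblast in EPISC, which fell short in the exact distribution, primitive endoderm in XEN and, below its bar, primitive endoderm in ESC.

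None of the lists for other cell types or signalling pathways passed the threshold in any of the 4 cell types. Markers of fibroblasts, which often serve as feeder cells, had EPISC-specific regions at 3 of 12 genes (Twist1, Prrx1 and Col3a1), with 83.0% of random lists lower, and specific regions at 2 in ESC, 2 in TSC and 1 in XEN. Neural markers had specific regions near 3 of 12 genes in ESC, 3 in EPISC, 2 in TSC and none in XEN. Blood markers had XEN-specific regions near 6 of 12, with 97.3% of random lists lower, TSC-specific regions near 5, ESC-specific regions near 5 and EPISC-specific regions near 1. All 12 housekeeping genes had a promoter peak in all 4 lists, and none had a XEN-specific region nearby, as in 0.28% of random lists. ESC-specific regions lay near 9 of them, TSC-specific regions near 6 and EPISC-specific regions near 1. Targets of FGF and ERK signalling had specific regions near 6 of 12 in TSC, 5 in XEN, 4 in ESC and 4 in EPISC. WNT targets had specific regions near 7 of 12 in TSC, with 91.9% of random lists lower, 5 in EPISC, with 96.3% lower, 5 in ESC and 2 in XEN. NODAL and BMP targets had specific regions near 6 of 12 in ESC, 5 in EPISC, 5 in TSC and 4 in XEN. Of the 48 combinations of list and cell type, 3 passed the threshold in either direction in the 10000 draws, where 0.096 were expected by chance. In the exact distribution over all matched lists, 1 passed above and 1 below, and primed genes in EPISC did not pass.

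**Figure D3:**
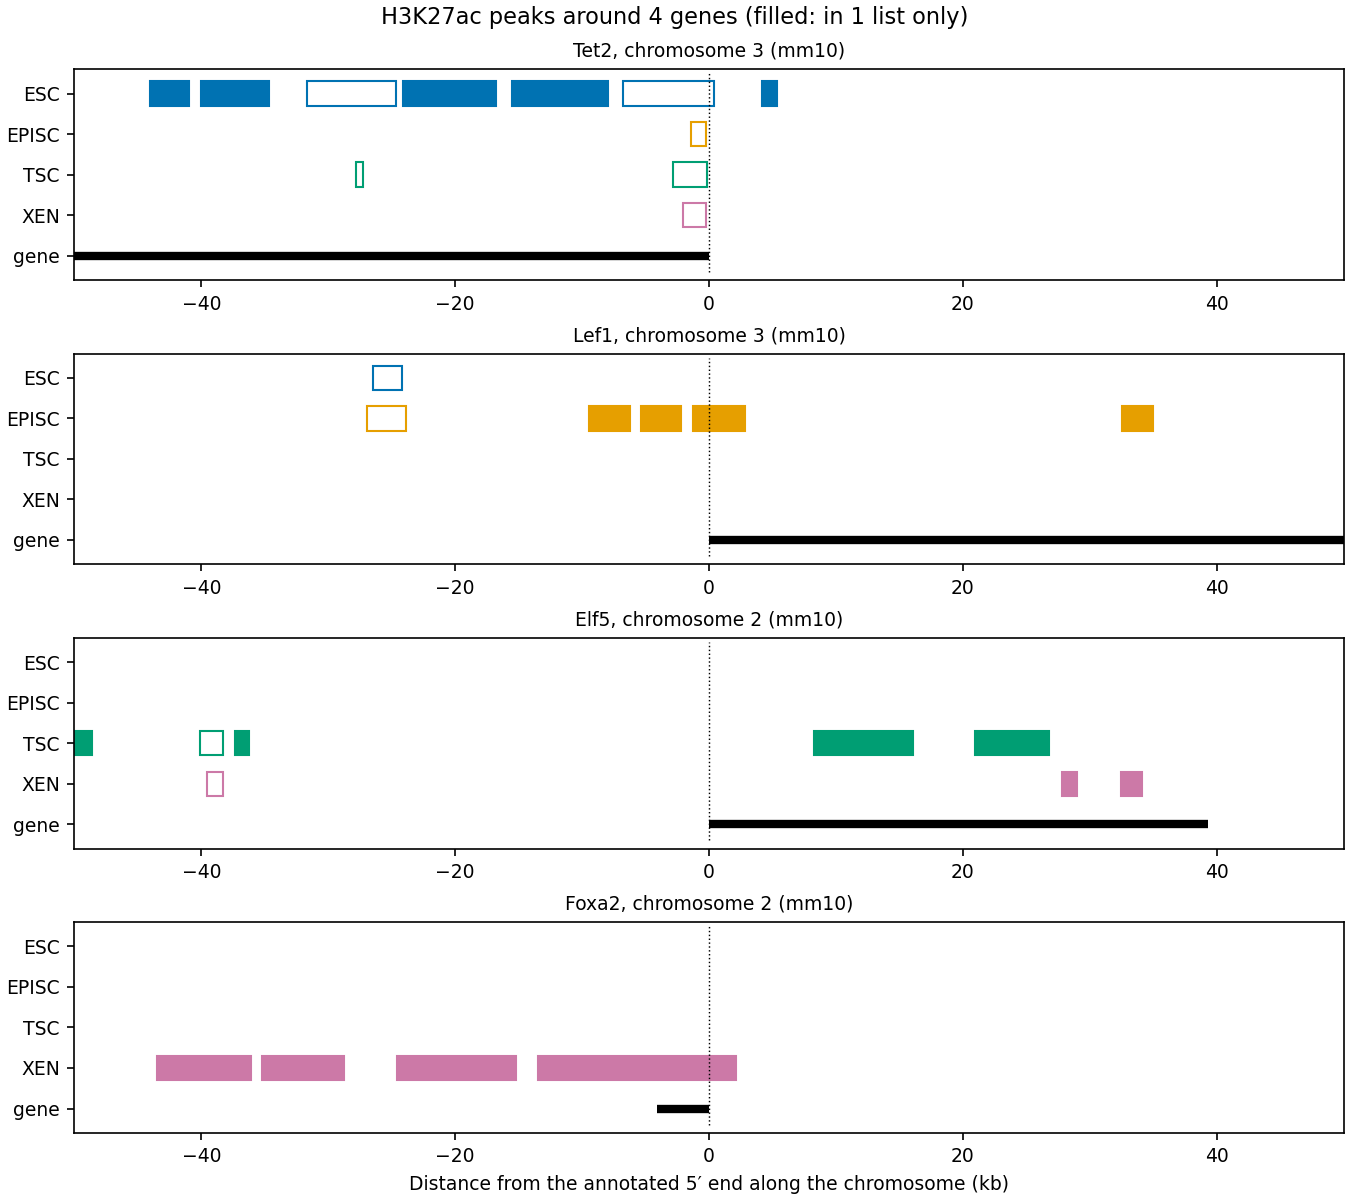
Peaks of the 4 lists (rows, boxes to scale) around the first-ranked gene of each cell type's own list, within 50 kb of the annotated 5′ end (horizontal axis, kb); filled boxes are peaks in 1 list only and the black bar is the gene. Tet2 has 5 ESC-specific peaks, Lef1 has 4 EPISC-specific peaks, Elf5 has 4 TSC-specific peaks beside 2 XEN-specific ones, and Foxa2 has 4 XEN-specific peaks and no other peak.

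Ranked by the length of specific regions assigned to the nearest gene start, the leading ESC genes were Rtn4 (12 regions), Pigl (37.5 kb) and Cobl (36.9 kb), followed by Ipo11, Pole4, Zmym4, Klf4, Morc3, Tet2 and Sdc3. The largest of the Klf4 regions, 21.4 kb on chromosome 4 (55461923 to 55483286), was intergenic and 49.2 kb from the start of Klf4, a pluripotency transcription factor. The leading EPISC genes were Sema3e (20.8 kb), Plekha1 (16.3 kb), Mfap3l (15.4 kb) and Lef1 (15.3 kb), whose largest region spanned its first exon (chromosome 3, 131109238 to 131113279). Myrf, Chd9, Sort1, Slfn3, Pim2 and Zfp322a followed. In TSC, Hand1 led with 34.3 kb in 9 regions, the largest of them intergenic on chromosome 11 (57907594 to 57918595), 74.8 kb from the gene. Atxn7l1 (32.4 kb) and Gramd4 (30.0 kb) came next, then Rbm20, Dysf, Lrrc8d, Snx27, Rin3, Dyrk1a and Ppp1cb. In XEN, the totals were larger, led by Ankrd33b (72.9 kb), Foxa2 (58.9 kb in 11 regions), Tcf7l2 (57.5 kb), Epas1 (52.6 kb), which encodes a hypoxia-inducible factor, and Cemip (49.0 kb). Bend5, Mical2, Lama1 (40.2 kb) and Podxl were among the 10. C9 (45.5 kb) also ranked there, but its largest region (chromosome 15, 6426152 to 6451080) was centred in an intron of the neighbouring endoderm gene Dab2. Likewise, the largest regions of Pigl and Sdc3 in ESC and of Pim2 in EPISC were centred in introns of Ncor1, Pum1 and Otud5. These ranks depend on what counts as specific. When a peak counted as shared only with at least 50% of it covered, none of the 10 ESC genes, 4 of the EPISC, 4 of the TSC and 6 of the XEN genes stayed among the first 10.

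The pair of pluripotent types was compared directly, since ESC and EPISC stand for successive states of the epiblast. ESC held 14471 peaks without an overlapping EPISC peak, 54.8% (54.2 to 55.4) of its list, and EPISC held 4842 without an ESC peak, 28.7% (28.0 to 29.4). Promoters made up 15.0% of the former and 25.4% of the latter. By nearest gene start, ESC-only peaks were longest at Tbx3 (61.4 kb in 10 peaks), Sik1 (59.5 kb), Pole4 (50.5 kb), Kat6b (50.2 kb), Bcat1 (47.5 kb) and Tfcp2l1 (46.3 kb), with Zbtb44, Rtn4, Jade1 and Plpp3 after them. Tbx3 and Tfcp2l1 are transcription factors of the naive network. EPISC-only peaks were longest at Zfp608 (22.3 kb), Pcdh1 (21.7 kb), Sema3e (20.8 kb), Chd9 (20.1 kb), Nfasc (20.1 kb), Trio, Mfap3l, Irf2bp2, Pou3f1 (17.8 kb in 5 peaks) and Plekha1. The 5 Pou3f1 peaks lay beside a gene that encodes a POU factor of the primed epiblast. Within 50 kb of its start, peaks covered 33.3 kb in EPISC, 31.6 kb in TSC, 8.39 kb in XEN and 0.992 kb in ESC. Acetylation there was thus not particular to EPISC. When a peak counted as shared only with at least 50% of it covered, 2 of the 10 ESC genes and 6 of the 10 EPISC genes stayed among the first 10, and with the wider 50% of each list 5 and 7 stayed. Of 12 NODAL and BMP targets, 10 had an EPISC-only peak within 50 kb, against a random median of 5, with 99.83% of random lists lower. Naive genes had ESC-only peaks at 17 of 18 (95.6% lower) and primed genes EPISC-only peaks at 10 of 17 (95.7% lower). Fibroblast (feeder cell) markers ranked as high as the primed genes, with EPISC-only peaks at 5 of 12 (95.8% lower). None of the 24 combinations of list and cell type passed the threshold. With a 20 kb window, NODAL and BMP targets reached 99.99% in EPISC, past the threshold. Naive genes passed it in ESC with a 20 kb window (99.97%), with the wider 50% of each list (99.91%) and with lists of equal size (99.99%). With lists of equal size they were also low in EPISC, where 0.01% of random lists had as few. There, with the ESC list cut and the EPISC list whole, ESC-only peaks numbered 8802 and EPISC-only peaks 8595.

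Regions held by exactly 2 lists asked whether embryonic and extraembryonic types pair up. ESC and EPISC, the embryonic pair, shared 1383 regions that neither TSC nor XEN held. TSC and XEN, the extraembryonic pair, shared 1277 regions held by neither pluripotent type. In the full lists, the largest pair crossed that division, with 1972 regions held by ESC and TSC alone. ESC and XEN alone held 974, EPISC and TSC 854, and EPISC and XEN 193. The order did not hold with lists of equal size. There, ESC and EPISC alone held the most, 1199 regions, followed by EPISC and TSC with 1163, ESC and TSC with 987, TSC and XEN with 935, ESC and XEN with 739 and EPISC and XEN with 728. Which pair was largest is therefore not settled by these lists. Regions in 3 lists but missing from the fourth were most often those XEN lacked, 1312 of the 9902 regions of the other 3 types (13.2%, 12.6 to 13.9). EPISC lacked 11.2%, ESC 5.86% and TSC 3.03%.

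Distal specific regions differed in the transcription factor motifs they held. Each of 20 consensus sequences was sought in their central 1 kb, and the share of regions with a match was set against 1000 draws, matched on GC content, from the distal specific regions of the other 3 types. Of 80 comparisons, 42 lay outside all draws, 18 above and 24 below. By chance 0.16 were expected if regions are independent and background shares are exact, and more if they are not. The backgrounds are shared, so a motif high in one type is lower in others by construction. TSC regions more often held matches of AP-1 (35.7% against a drawn median of 21.9%), TEAD (28.0% against 20.4%), TFAP2 (15.2% against 10.8%), T-box (6.54% against 4.58%), CDX (4.43% against 3.19%), CTCF (1.56% against 0.886%) and CREB (1.37% against 0.803%). TEAD, TFAP2, T-box and CDX families include the trophoblast regulators TEAD4, TFAP2C, EOMES and CDX2. XEN regions more often held GATA (14.5% against 7.71%), SOX (13.5% against 7.91%) and HNF4 (2.56% against 1.39%), families of GATA4, GATA6, SOX17 and HNF4A. EPISC regions more often held ZIC (37.7% against 28.1%), AP-1 (34.5% against 24.2%) and OCT (12.1% against 5.83%). ESC regions more often held OTX (21.3% against 15.4%), KLF (18.6% against 13.9%), ESRRB (6.29%, with draws from 1.77% to 2.77%), OCT (6.87% against 6.09%) and ETS (1.75% against 1.27%).

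Below all draws were AP-1 in ESC (19.4% against 29.9%) and in XEN (20.9% against 27.5%), OCT in XEN (4.05% against 7.06%), ESRRB in EPISC (1.10% against 4.26%) and GATA in ESC (7.04% against 10.6%), among others. The combined OCT-SOX consensus matched 13 of 2557 EPISC regions and 26 of 8690 ESC regions, within the draws. Part of the ESC result lay in repeats. Counting only matches outside repeat-masked bases, a check added after the data were seen, ESRRB stayed above all draws in ESC (2.73%), while OTX (6.26% against 7.02%), KLF (10.2% against 9.51%), OCT and ETS did not. The same count kept all 3 EPISC motifs, 6 of the 7 TSC motifs (CDX was lost) and all 3 XEN motifs, and added FOXA (11.6% against 8.77%) and HNF1 in XEN.

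**Figure D4:**
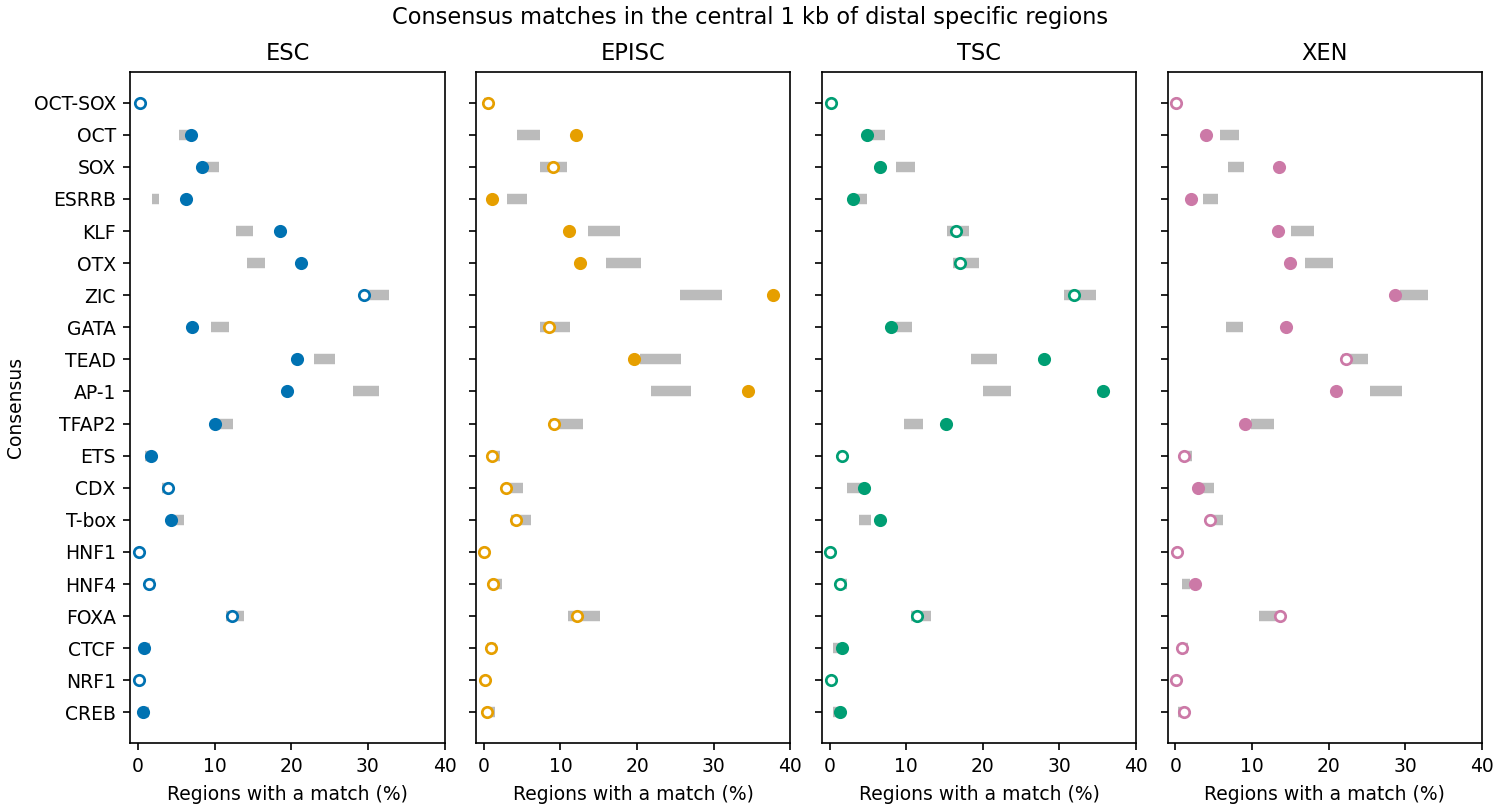
Circles give the share of distal specific regions (percent, horizontal axis) with a match of each consensus in their central 1 kb, 1 panel per cell type; grey bars span all 1000 GC-matched draws from the other 3 types, and filled circles lie outside them. AP-1 and TEAD stand out in TSC, GATA and SOX in XEN, ZIC, AP-1 and OCT in EPISC, and OTX, KLF and ESRRB in ESC.

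Neighbouring peaks were joined into clusters and ranked by the summed length of their peaks, which describes extent and not signal. The largest ESC clusters lay at Tgif1 (98.7 kb of peaks, chromosome 17, 70737574 to 70925773), Usp7 (98.0 kb), C77080 (85.1 kb), Tns3 (83.4 kb) and Cd9 (81.9 kb). In TSC they lay at Tead1 (145.1 kb of peaks, chromosome 7, 112677889 to 112870036), which encodes a TEAD factor, Flnb (102.0 kb), Rbm20 (93.1 kb) and Myh9 (86.4 kb). A further stretch, centred outside protein-coding genes and nearest to Myc, held 84.2 kb (chromosome 15, 62037656 to 62147831). The other lists covered between 9.28 and 13.8 kb of that stretch. In XEN they lay at Ptpn14 (139.0 kb of peaks, chromosome 1, 189726512 to 189886784), Flnb (123.8 kb), the paired collagen genes Col4a1 and Col4a2 (113.6 kb), a stretch holding Adamts9 and named Gm15737 by its nearest gene start (108.3 kb), and a stretch without a gene start, nearest to Pmfbp1 (104.7 kb). These XEN clusters all lay on chromosomes 1, 6, 8 and 14. At regions in all 4 lists there, the median log2 width ratio of XEN to the mean of the other lists was raised. It lay 0.25 to 0.31 above the median of autosomes, so the ranks may owe part of their length to these chromosomes. Across the Col4a1 and Col4a2 cluster, TSC peaks covered 17.0 kb, and EPISC peaks covered 1.35 kb and ESC peaks slightly less. The widest XEN peak, 61.8 kb on chromosome 11 (82803582 to 82865412), was centred in an intron of Rffl. In EPISC the largest cluster covered 14 replication-dependent histone genes of the Hist1 locus (55.7 kb of peaks, nearest gene Hist1h2bh), and Cxxc5 (40.4 kb), Pmepa1 (39.0 kb), Chd9 (36.8 kb) and Myh9 (35.5 kb) followed. Clusters with at least 50 kb of peaks numbered 55 in ESC, 29 in TSC, 28 in XEN and 1 in EPISC. With a joining distance of 5 kb they numbered 17, 13, 14 and 0, and from distal peaks alone 6, 7, 9 and 0.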

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

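No paired analysis was possible because the values analysed here are 1 peak list per cell type, named by the labels of both replicates, and for the same reason no replicate could be left out. The labels also name a signal track per replicate, which was not analysed here and could allow such a comparison. Depth and peak scores are unknown, so width stood in for strength. Of 148 alternative values of the main results, 83 kept their call or stayed close to the main value. The main values that moved follow, and the cause was not tested unless stated.

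With the wider 50% of each list, overlaps fell to 56.9% of EPISC, 49.0% of TSC and 43.9% of XEN peaks in the ESC list, 60.7% of EPISC and 51.3% of XEN peaks in the TSC list, and 43.7% of EPISC peaks in the XEN list. Specific regions numbered 5766 in ESC, 3765 in TSC and 3726 in XEN, which follows from fewer peaks, and the promoter share of regions in 1 list was 22.4%. ESC peaks not in EPISC numbered 8474. ESC and EPISC alone held 793 regions, ESC and TSC 1172, and ESC and XEN 581. Naive genes in ESC rose to 99.99%, past the threshold, and primitive endoderm genes in ESC lost their low call (3.77%). In ESC, 3 motifs stood above all draws, and the CTCF difference turned to 0.0608 points above the drawn median.

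With all lists at the smallest size, the same overlaps were 49.1%, 50.4% and 44.9% in the ESC list, 57.9% and 54.9% in the TSC list and 52.1% in the XEN list. Specific regions numbered 6151 in ESC, 4626 in EPISC and 4138 in TSC, which turns the order of TSC and EPISC. The EPISC list kept all its peaks, so its specific regions rose only because peaks of the other lists were dropped. The promoter share in 1 list was 16.9%. ESC-only peaks numbered 8802 and EPISC-only peaks 8595 in the direct comparison. ESC and TSC alone held 987 regions and EPISC and XEN 728, and the largest pair was ESC and EPISC with 1199. Naive genes in ESC reached 100%, and primed genes in EPISC fell to 99.89%, short of the threshold. In ESC, 3 motifs stood above all draws, and ETS turned to 0.127 points below the drawn median (-0.127).

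With sharing defined as 50% of a peak covered, overlaps were 65.3% of EPISC, 48.2% of TSC and 48.6% of XEN peaks in the ESC list, 65.2% of EPISC and 53.4% of XEN peaks in the TSC list and 54.3% of EPISC peaks in the XEN list. TSC and XEN alone held 1970 regions. With peaks within 1 kb counted as shared, they were 59.7% of TSC and 59.4% of XEN peaks in the ESC list and 62.5% of XEN peaks in the TSC list, and primed genes in EPISC fell to 99.6%. A promoter distance of 1 kb gave a promoter share of 9.15% for regions in 1 list. A distance of 5 kb gave 21.5%, and 91.3% for regions in all 4.

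Primed genes in EPISC also lost their call with a 20 kb window (99.69%), a 100 kb window (99.25%), the exact distribution (99.8999%) and neighbouring members counted once (99.89%). Trophoblast genes in TSC gained one with a 100 kb window (99.93%) and with distal regions only (99.97%). Without matching, naive genes in ESC and trophoblast genes in TSC each reached 100%.

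A motif window of 500 bp left 3 motifs above all draws in ESC. Counting matches outside repeats only, chosen after seeing the data, left 1 in ESC and gave 5 in XEN. By that count, differences from the drawn median turned for OTX in ESC (-0.759 points), OTX in XEN (0.733), KLF in XEN (0.251) and ZIC in XEN (0.174), none of them outside the draws. Clusters with at least 50 kb of peaks numbered 17 in ESC, 0 in EPISC, 13 in TSC and 14 in XEN with a joining distance of 5 kb, and 6, 0, 7 and 9 from distal peaks only, as shorter joins and fewer peaks must give.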

Other observations

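The comparisons of regions held by 2 lists, and the counts of repeats, distances and other transcript starts, were chosen after the region classes had been seen, whereas the predictions for the 6 tests below were written before those tests were run.

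Regions held by 2 cell types alone also grouped lineage genes, several of which had specific regions as well. Of 17 primed epiblast genes, 9 had a region held by ESC and EPISC alone within 50 kb, among them Otx2, Foxd3, Nodal, Cdh2, T and Zic2, against a random median of 2, and all 10000 random lists were lower. Primitive endoderm genes stood out at regions held by ESC and XEN alone, with 8 of 22, including Gata6, Hnf4a, Dab2 and 3 laminin genes, and 99.93% of random lists lower. Of 72 such comparisons, these were the 2 past the threshold. They were run at the main settings alone, so whether the calls hold under the alternatives is unknown. The primed count holds both Zic2 and Zic5, whose starts lie close together, and the 99.93% lies near the threshold. Distal regions held by ESC and XEN alone matched the SOX consensus at 14.5%, against a drawn median of 7.54%. Those of EPISC and TSC alone matched AP-1 at 46.2% against 25.2%, and CTCF at 3.26% against 0.906%, and those of TSC and XEN alone matched GATA at 13.1% against 8.74%. Of the 12 motif results above all draws at such regions, 5 stayed there outside repeats, these 4 and OCT at regions of EPISC and TSC alone, and 7 did not. Those lost were OCT and ETS for ESC and EPISC, ESRRB, KLF, OTX and T-box for ESC and TSC, and CDX for EPISC and XEN.

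Distal specific regions differed in where they lay. Their median distance to the nearest protein-coding gene start was 53.7 kb in EPISC, 38.2 kb in XEN, 29.1 kb in ESC and 26.6 kb in TSC, and 35.2% (33.3 to 37.1) of the EPISC regions were more than 100 kb away. Centres made up mostly of repeats were more frequent in EPISC (17.1%, 15.7 to 18.6) and ESC (15.2%, 14.4 to 15.9) than in TSC (6.76%) and XEN (4.17%). Of the 847 distal regions in all 4 lists, 36.1% (32.9 to 39.5) lay near a transcript start of another gene type, against 10.2% of those in 1 list.

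XEN peaks were dense on chromosomes 14, 16 and 19, with shares 1.31, 1.23 and 1.31 times the mean of the other lists. Extra copies would widen peaks there even at regions present in all 4 lists. Their median log2 width ratio was on average 0.34 (0.30 to 0.39) above that of the other autosomes, as extra copies would give. The interval resamples regions of these chromosomes only, and the SD between the other autosomes was 0.149. Without the 10% of 1 Mb bins richest in XEN peaks over the whole genome, the lowest share ratio was 1.24. How much of chromosomes 14, 16 and 19 those bins held is unknown. The test therefore cannot decide whether a few dense stretches account for the shares of these chromosomes. Chromosomes 1, 6, 8, 12 and 15 also had share ratios over 1 and wider peaks, and the other 11 autosomes had ratios of 0.851 to 0.980. Copy number and higher acetylation of whole chromosomes cannot be told apart by peak lists. The XEN genes and clusters on these chromosomes may owe part of their length to either.

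EPISC peaks were dense on chromosome X, which held 1.47 times the mean share of the other lists. At 190 X-linked regions present in all 4 lists, the median log2 width ratio was 0.34 (0.26 to 0.41) above that of autosomes. The interval resamples regions of X only, and the SD between autosomes was 0.0662. Such an excess is what more signal from the whole chromosome would give. Without the 10% of 1 Mb bins richest in EPISC peaks over the whole genome, the share ratio was 1.55. X held 465 of the 16873 EPISC peaks, so those bins may have held little of it. The test therefore cannot decide whether a few dense stretches of X account for its share. More X copies, a second active X or a difference between lines would each raise the share of X, and the labels used here do not settle which.

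ESC held 3.17 times as many specific regions as EPISC. At the 8590 regions in all 4 lists EPISC peaks were narrower than ESC peaks by a median log2 ratio of -0.13 (-0.15 to -0.11), with 59.2% of them narrower, which is consistent with a lower sensitivity of the EPISC list. With lists of equal size, a setting fixed in advance whose ratio was taken after the data were seen, ESC held 1.33 times as many. That setting leaves the EPISC list whole and drops narrow peaks of the others, so part of this fall follows from the trimming. In the wider 50% of each list ESC held 2.72 times as many. Whether narrow ESC peaks near the calling threshold account for part of the difference stays undecided. A real loss of distal acetylation in the primed state would also give more ESC-specific regions, and depth per sample would be needed to separate it from sensitivity.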
